A study of Aspergillus fumigatus with 2 samples.

How the data were processed

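Total RNA (7 µg) of untreated and AMB-treated cultures was reverse transcribed with labelled nucleotides, amplified by tyramide signal amplification and hybridised to 2 two-colour arrays, per the labels' protocols. The authors deposited scanner exports for both arrays. Per the file headers, these hold the foreground and local background intensity of each spot at 635 nm (red) and 532 nm (green), not background subtracted and not normalized. The deposited exports also give percent columns, namely the share of spot pixels above background or saturated and the GC content of the probe. The authors' value table holds a linear ratio per probe. Every deposited ratio equalled the 635 over 532 nm foreground mean times 1 constant per array, to within 1.57e-08 on the log2 scale. The ratios were therefore neither background subtracted nor turned for the dye swap, and their medians were 0.765 for array 1 and 1.92 for array 2. What the constants were chosen to achieve stays unknown, and the scanner software is not given in the sources used here.

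Of 10503 spots in 24 blocks, 9654 carried 70-base probes for 9626 genes of strain Af293. Gene names and products are those of the array files; 9202 of the genes matched a locus tag of the annotation of assembly ASM265v1, which gave a symbol for 1361. The files name no genome build, so no coordinates are given. No spot was flagged. Background was corrected with normexp (offset 50) on the foreground mean and the local background median, with all spots. Global loess was fitted within each array, with control and obsolete probes at weight 0. A spot was left out where neither channel exceeded its local background on that array, which removed 993 gene probes on array 1 and 1953 on array 2. Probes of a gene were averaged; 14 tested genes had several probes, in 8 of these the probes differed in sign, and none of the 14 is named in the text. This left 7391 genes with ratios on both arrays, and 2235 genes were not tested.

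The log2 ratio of AMB over untreated was tested against 0 with lmFit and eBayes of limma (version 3.58.1, R 4.3.3), with an intensity trend in the prior and Benjamini-Hochberg adjustment at 0.05. Array 1 was read by its dye labels and array 2 was turned. Array, biological replicate and dye orientation coincide and cannot be told apart, and a dye effect could not be fitted with 2 arrays. A dye effect common to both arrays cancels in the mean only if the arrays do run in opposite orientation. Gene lists were tested with camera on the z-scores of the fit with a preset inter-gene correlation of 0.01, and camera with an estimated correlation and fry were alternatives. A list needed 5 measured members.

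A channel was called well above background where its normalized signal, after loess and Aquantile scaling between arrays, exceeded the 95th percentile of the 500 control spots in that channel. By construction 5 percent of the control spots pass it. A gene above it on 1 of the 2 arrays was counted as above background in that RNA. A gene above it on no array in an RNA has only a bound there. The bound sets the mean of the brighter RNA against the higher of the dim signal and the lowest signal above background, is written as "at least N-fold", and is open to dye bias. No fold is given for genes above background in neither RNA.

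The groups, the tests, the 18 gene lists, the rule for named genes and most of the alternative settings were set before the data were examined. Background by control spots and 6 alternatives were chosen after the data were seen, and these are the foreground median, a filter by control spots, the centred value table, subtraction of neighbouring spots, a GC correction and a DNA replication list without part-word matches. Named genes were the 10 largest in each direction among called, named genes with the same sign on both arrays. This was filled up with genes at least 2-fold on both arrays, ranked by the smaller size. To these were added up to 4 members of each list and a fixed set of sterol, oxidative stress, gliotoxin, cell wall and conidial genes. The alternative settings fixed at the outset covered the background correction, the normalization within and between arrays, the filter, the value table, the dye orientation, the eBayes settings and each replicate left out.

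The steps were tested on 2 simulated arrays with 9426 genes in the fit. The changed genes were drawn only from the brightest probes. Each channel had a constant local background, noise had the same size for every spot, and array 2 was simulated as the swap. Of 100 genes changed by a log2 size of 2, 81 were recovered at a median estimated size of 1.77, and of 100 changed by 3, 100 were recovered at 2.56, with 6 false calls. These shares check the steps and do not give the power for the real arrays, where most probes were dim. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.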

Results

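The transcript levels of the mould Aspergillus fumigatus grown with and without amphotericin B (AMB) were measured on 2 two-colour oligonucleotide arrays. AMB is a polyene antifungal drug that binds ergosterol, the main sterol of the fungal membrane. Conidia, the asexual spores, were grown for 24 h at 37 °C in RPMI-1640 medium, alone or with the drug at the MIC50. Each array set RNA of an AMB culture against RNA of an untreated culture, and the arrays came from 2 biological replicates with the dyes meant to be exchanged between them. The arrays carried 9654 probes for 9626 genes of strain Af293, 500 Arabidopsis control spots and 349 probes listed as obsolete. The number of arrays limits the precision of every value.

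Which RNA lay in which channel was not settled by the labels. The dye labels put untreated RNA in Cy5 and AMB RNA in Cy3 on both arrays, whereas the description of replicate 2 and the series design call it a dye swap. Directions here follow array 1 as its dyes are labelled with array 2 turned. They are called likely, because array 2 is the array described as the swap, so the dyes of array 1 stand. If the dye labels of array 2 were right and array 1 were the swapped array, every "higher" and "lower" would exchange. With both arrays read by their dye labels, no gene passed the limma test, and 259 had an unadjusted p under 0.05. The unturned log2 ratios of the arrays correlated at Pearson r = -0.45 across gene probes before normalization and at -0.14 after it (Spearman's rho -0.39 and -0.08). Genes are not independent replicates, and the control spots alone gave r = -0.40 before and -0.09 after normalization.

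Most probes were dim. The share of gene probes brighter than the 95th percentile of the control spots was 17.8% and 14.7% in the red and green channels of array 1, and 17.1% and 23.1% in those of array 2. In the red channel of array 2, which likely held AMB RNA, 12.3% of gene probes exceeded their local background, against 79.5% to 85.0% in the remaining channels. Gene spots with a large share of saturated pixels numbered 28 in the red channel of array 1 and 44 in the green channel of array 2. Both channels likely held untreated RNA, and the 2 likely AMB channels had 0. Saturation of the untreated RNA alone would raise the ratio of AMB over untreated of the brightest genes. Which genes it touched was not examined. The correlation of the turned ratios across genes went with brightness. It was -0.01 over the 5912 probes above the control spots in no channel and 0.42 over the 494 above them in all 4 channels.

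**Figure D1:**
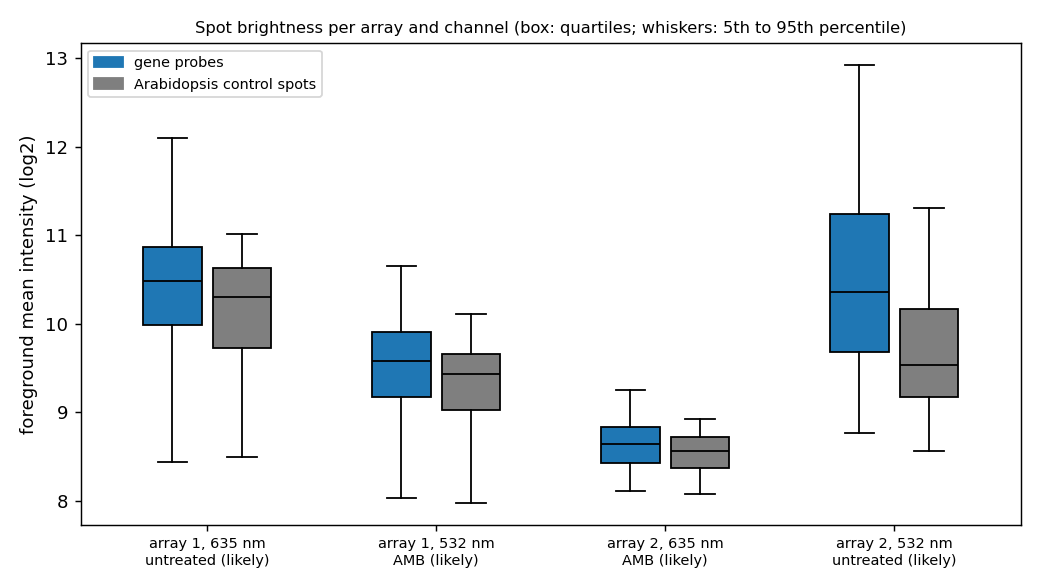
Foreground mean intensity (log2) of the gene probes (blue) and the Arabidopsis control spots (gray) in each channel of each array, with boxes at the quartiles and whiskers at the 5th and 95th percentiles. The control spots overlap much of the range of the gene probes in every channel, and the red channel of array 2 is the dimmest, with a median of 398 for gene probes against 377 for control spots.

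The comparison of AMB against untreated cultures asked which transcripts differed after growth with the drug. In the likely orientation, the gene with the smallest adjusted p was tef1 (Afu1g06390), which encodes translation elongation factor EF-1 alpha, the protein that brings aminoacyl-tRNAs to the ribosome. It rose 19.6-fold, with a log2 ratio of 4.29 ± 0.62 (SD, n = 2) and an adjusted p of 0.0206 in limma. Its size depended on the processing, with a log2 ratio of 1.65 under median centring in place of loess and a range of 0.63 to 5.16 over 15 alternative settings, and it passed in 8 of these. Such ranges of single genes leave out each array alone and the reading of both arrays by their dye labels, which put tef1 at -0.44. A putative cell wall protein (Afu3g08110) rose 11.6-fold, at a log2 ratio of 3.53 ± 1.68 (SD, n = 2), and a putative membrane protein with a DUF221 domain (Afu5g10920) rose 9.21-fold, at 3.20 ± 0.37 (SD, n = 2). In the untreated RNA Afu5g10920 was well above background on 1 of the 2 arrays only. A putative amino acid permease (Afu5g00930) and a putative multidrug transporter of the major facilitator superfamily (Afu3g01940) also rose, at log2 ratios of 2.42 ± 0.46 and 2.17 ± 0.19. Both were not well above background in the untreated RNA, so their folds are bounds of at least 1.13-fold and at least 1.63-fold, open to dye bias. In the AMB RNA Afu5g00930 was well above background on 1 of the 2 arrays only. The rises beside tef1 depended on the processing as well. Over the same alternative settings the log2 ratio ranged from 0.94 to 3.88 for Afu3g08110 and from 0.34 to 4.05 for Afu5g10920, each passing in 8 of 15. It ranged from 0.60 to 3.15 for Afu5g00930, which passed in 6 of 13, and from 1.02 to 3.11 for Afu3g01940, which passed in 8 of 12. Outside these ranges, both arrays read by their dye labels put Afu5g10920 at -0.26 and Afu5g00930 at -0.33.

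Among the genes that fell with AMB in the likely orientation was Afu8g01530, a protein with an HHE domain, a fold related to the iron-binding hemerythrins. It was 11.1-fold lower, with a log2 ratio of -3.48 ± 1.46 (SD, n = 2). Afu3g11550 encodes a protein with a late embryogenesis abundant (LEA) domain, a family known from desiccation tolerance, and was 8.91-fold lower at -3.16 ± 0.92 (SD, n = 2). In the AMB RNA both genes were well above background on 1 of the 2 arrays only, so these folds rest partly on dim signal. Over the alternative settings Afu8g01530 ranged from -5.11 to -2.82 and Afu3g11550 from -4.76 to -1.84, each passing in 9 of 14. These ranges too leave out the reading by the dye labels and each array alone, where Afu8g01530 had -4.51 and -2.45. The remaining 3 genes that fell carried no functional name. These were Afu2g15810 at -3.57 ± 1.93, Afu5g13100 at -3.39 ± 1.26 and Afu8g02250 at -2.51 ± 0.47. The last was not well above background in the AMB RNA, which bounds it at at least 3.07-fold lower. Each of these genes had the same adjusted p of 0.0467 in limma as the 4 genes that rose beside tef1, and all 10 had fitted ratios of at least 2-fold in the same direction on both arrays. These p-values rest on 2 biological replicates.

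**Figure D2:**
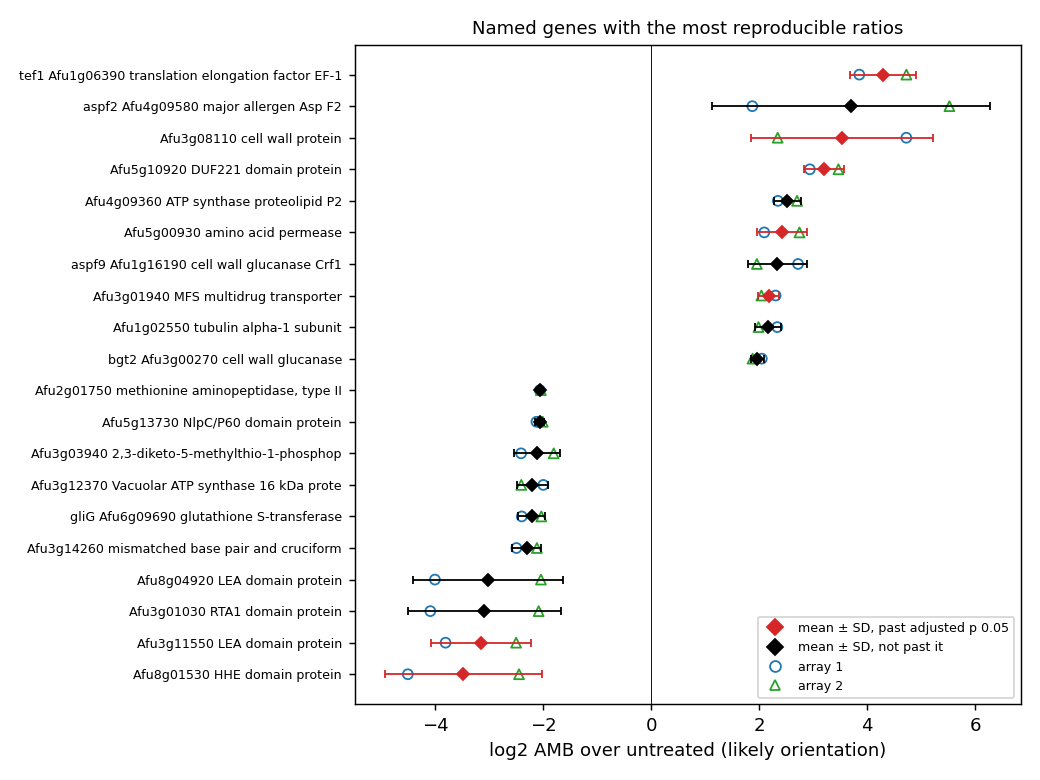
Log2 ratio of AMB over untreated in the likely orientation for the 20 genes named by a rule on size and reproducibility, with circles for array 1, triangles for array 2 and diamonds with bars for the mean ± SD of both. The 7 red genes passed the limma test, tef1 at 4.29 being the highest and Afu8g01530 at -3.48 the lowest.

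Several genes of similar size missed the test. A second LEA domain protein (Afu8g04920), well above background in the AMB RNA on 1 of the 2 arrays only, had a log2 ratio of -3.02 ± 1.39 and an adjusted p of 0.0517 in limma. For a membrane protein with an RTA1 domain (Afu3g01030) the values were -3.09 ± 1.42 and 0.0531. The major allergen Asp f 2 (Afu4g09580) stood at 3.70 ± 2.58, with 1.87 on array 1 and 5.52 on array 2, at an adjusted p of 0.0672. Its probe was bright, at a mean log2 brightness of 15.3, and saturation of the untreated RNA was not examined for it. The proteolipid subunit of a putative ATP synthase (Afu4g09360) had a log2 ratio of 2.52 ± 0.25, and the proteolipid subunit of the vacuolar ATP synthase (Afu3g12370) had -2.20 ± 0.29. The cell wall glucanase Crf1 (Afu1g16190) stood at 2.34 ± 0.54 and an alpha-tubulin (Afu1g02550) at 2.16 ± 0.25, but with median centring in place of loess the tubulin pointed the other way. Under that setting Crf1 lay at 0.10, Afu4g09360 at 0.05 and Asp f 2 at 0.42, whereas the genes of this paragraph that were lower with AMB moved further from 0.

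In all, 10 of the 7391 genes tested passed, 5 higher and 5 lower with AMB. An unadjusted p under 0.05 was found for 560 genes, against 369.55 that chance would give. At least 2-fold ratios in the same direction on both arrays were found for 192 genes, 70 higher and 122 lower. The count expected from independent arrays was 73.2, and 34 genes were at least 2-fold in opposite directions. Of the 70 higher genes, 50 were well above background in both RNAs and 18 in the AMB RNA alone. Of the 122 lower genes, 61 were above it in both and 57 in the untreated RNA alone. The counts rest on fitted ratios, so a gene above background in a single RNA can have a bound under 2-fold. With the signs turned, 122 genes would be higher and 70 lower. Over all tested genes 51.9% had the same sign on both arrays.

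**Figure D3:**
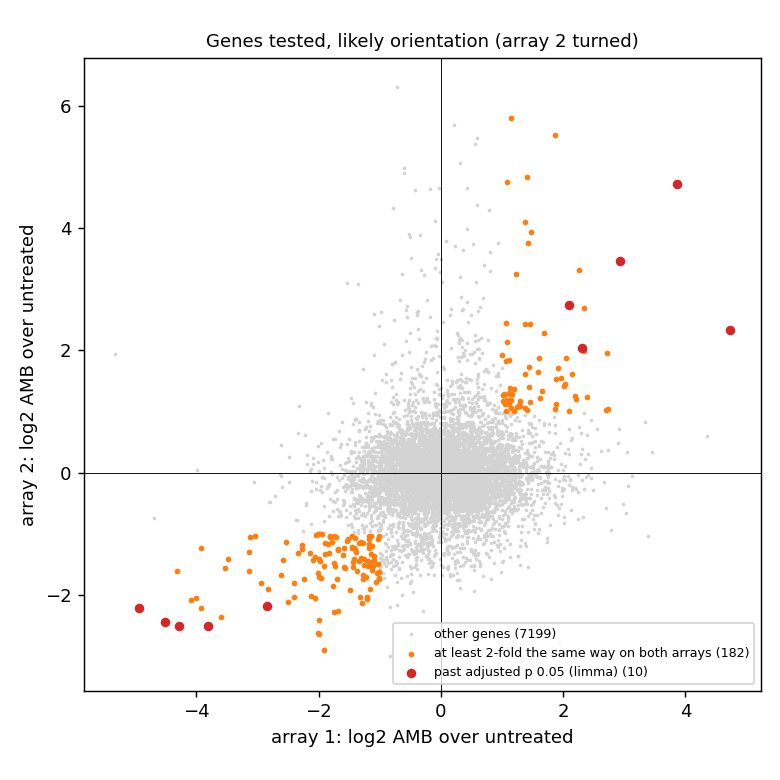
Log2 ratio of AMB over untreated on array 1 (x axis) and array 2 (y axis) for each of the 7391 genes tested, in the likely orientation. The 10 genes past the adjusted p threshold (red) lie in the upper right and lower left corners, and the 192 genes at least 2-fold in the same direction (red and orange together) outnumber the 34 in the opposite quadrants beyond 2-fold.

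Both the number of calls and the balance of directions depended on the processing. The count of genes past the adjusted p ranged from 0 to 277 over the alternatives, and with median centring in place of loess the 2-fold genes split into 34 higher and 564 lower. That setting placed the median of all tested genes at -0.18 on the log2 scale. It left all 122 lower genes lower, but turned 32 of the 70 higher genes to the other side. Because median centring moved the balance toward lower, it could hardly turn the lower genes, and their staying lower is no sign of robustness. The deposited ratio table has a median log2 ratio over genes of 0.38 on array 1 and 0.90 on array 2 once turned, so directions read from it are relative to that shift. Some of the lower genes turned sign there, among them gliJ (Afu6g09650) at 0.51, mirC (Afu2g05730) at 0.08 and Afu1g15820 at 0.007. The 7 called genes with a product name kept their sign under each of these scalings, but the size of several changed. With median centring Afu3g08110 stood at a log2 ratio of 1.20 and Afu5g10920 at 1.69, while Afu8g01530 stood at -5.11 and Afu3g11550 at -4.76.

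The 18 gene lists fixed beforehand were compared with all other genes. No list passed camera, a competitive gene set test in limma, after adjustment; 2 lists had an unadjusted p under 0.05 with the preset correlation, and none did with an estimated correlation. fry, which tests whether the genes of a list move on balance one way, also called no list. With 2 arrays, fry and camera with an estimated correlation have little power, so their lack of calls does not weigh against a list. The list closest to the threshold was that of secreted peptidases, for which 33 of 45 measured members had log2 ratios above 0, with a median of 0.29 and an adjusted p of 0.0695. With an estimated correlation its adjusted p was 0.806, and it passed with block loess, without the trend and with the foreground median. The secreted dipeptidyl peptidase dppV (Afu2g09030) had 1.50 ± 0.53 and turned sign with median centring. A putative carboxypeptidase (Afu1g00420) had 1.66 ± 0.97, whereas a putative methionine aminopeptidase (Afu2g01750), an intracellular enzyme caught by the name pattern, had -2.05 ± 0.01. The latter was the 1 member called when p-values were adjusted over the list alone. Here and below, that adjustment was made in each list apart, with no correction over the 18 lists. Passing it is therefore weaker than passing over all genes.

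Genes of ergosterol synthesis, the pathway of the drug's target, showed no detected shift as a group, but 10 of the 26 measured were above the control spots in neither RNA. Of 26 measured members, 12 lay above 0 and 14 below, with a median of -0.04 and an adjusted p of 0.989 in camera, whose statistic lay barely above that of other genes. No member passed, over all genes or adjusted over the list alone. erg6 (Afu4g03630), the sterol C-24 methyltransferase, was at -1.38 ± 0.52 and was the only member at least 2-fold in the same direction on both arrays. The demethylase gene cyp51B (Afu7g03740) stood at -0.20 ± 0.31, erg25 (Afu8g02440) at 0.46 ± 0.11 and hmg1 (Afu2g03700), for HMG-CoA reductase, at 0.26 ± 0.78, with adjusted p of 0.980, 0.914 and 0.968 in limma. erg25 turned sign with median centring, and hmg1 with the centred value table. One of the ERG3 desaturase genes (Afu2g00320) had 0.09 ± 0.04. The regulator srbA (Afu2g01260) pointed in opposite directions on the arrays, with -0.25 and 0.97. Lipid genes other than sterols, 36 in number, had a median of -0.03 (adjusted p = 0.631). None passed over all genes and 2 passed adjusted over the list alone, namely a putative fatty acid hydroxylase (Afu1g15820) at -1.45 ± 0.02 and the sphingolipid transporter ncr1 (Afu6g09980) at -1.47 ± 0.18, both not well above background in the AMB RNA.

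Of 113 cell wall genes, 63 had ratios above 0 and 50 below, with a median of 0.05 and an adjusted p of 0.631. The 1 member that passed, also adjusted over the list alone, was Afu3g08110. Members that missed it included the glucanase bgt2 (Afu3g00270) at 1.96 ± 0.12 and the glucanosyltransferase gel4 (Afu2g05340) at 1.72 ± 0.65, both of which turned sign with median centring. The glucan synthase gene fks1 (Afu6g12400) had 0.26 ± 0.18 and also turned under that setting. Among 63 drug efflux transporters the median was 0.02 (adjusted p = 0.827). Afu3g01940 rose, and adjusted over the list alone 2 members passed, the second being gliA.

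The gliotoxin cluster, which makes and exports an epipolythiodioxopiperazine toxin, held members with large ratios of both signs. The efflux pump gliA (Afu6g09710) stood at 2.70 ± 1.75 and the transcription factor gene gliZ (Afu6g09630) at 1.12 ± 0.004. The glutathione S-transferase gene gliG (Afu6g09690) had -2.22 ± 0.26 and the dipeptidase gene gliJ (Afu6g09650) -1.82 ± 0.73, the latter not well above background in the AMB RNA and so bounded at at least 1.47-fold lower. All 12 members missed the test over all genes, and gliA, gliG and gliJ passed when adjusted over the list alone. The list's median was 0.31, its adjusted p 0.782, and with median centring the list was called lower (adjusted p 3.15e-04, within a range of 7.77e-05 to 0.977 over its alternatives), where gliA and gliZ also lay below 0. gliP (Afu6g09660), the peptide synthetase of the pathway, had 0.68 ± 0.07 and gliT (Afu6g09740), the oxidoreductase of self-protection, 0.72 ± 1.46. With median centring gliT turned sign, and gliP did so without background correction. The wider list of 33 polyketide and peptide synthases had a median of 0.06 (adjusted p = 0.631), with no call over all genes or adjusted over the list alone.

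Of 39 oxidative stress defence genes, 25 lay below 0 and 14 above, with a median of -0.18 and an adjusted p of 0.631, and no member passed in either adjustment. With median centring and with both forms of the value table the list was called lower than other genes, at a median of -1.01 and an adjusted p of 3.32e-05 with median centring, within a range of 3.32e-05 to 0.926 over its alternatives. The mycelial catalase gene cat1 (Afu3g02270) had 1.47 ± 0.65 and the cytochrome c peroxidase gene ccp1 (Afu4g09110) 1.81 ± 0.14, both turning sign with median centring, and sod1 (Afu5g09240) had -0.59 ± 1.19. Respiratory chain genes leaned lower, with 30 of 49 below 0, a median of -0.20 and an unadjusted p of 0.0368 that became 0.331 after adjustment. With an estimated correlation, which has little power on 2 arrays, the adjusted p was 0.806. This list too was called lower under the same 3 settings, at a median of -1.44 and an adjusted p of 2.66e-06 with median centring, within a range of 1.75e-09 to 0.806 over its alternatives. All 3 settings lack the loess on brightness, so for both lists they are not separate support. Adjusted over the list alone 2 members passed, Afu4g09360 above 0 and Afu3g12370 below it; the latter belongs to the vacuolar proton pump rather than to respiration. Glycolysis and citric acid cycle genes (49) had a median of 0.15 (adjusted p = 0.631). A putative fumarate hydratase (Afu6g02470) had 1.58 ± 0.20 and an NAD-dependent malate dehydrogenase (Afu7g05740) -1.30 ± 0.31.

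Cytosolic ribosomal proteins (65) had a median of 0.08 and an adjusted p of 0.631, but the list was called in both directions under other settings. It was lower than other genes with median centring (median -1.41, adjusted p 4.72e-06) and both forms of the value table, and higher with the foreground median (adjusted p 0.0356), within a range of 7.18e-09 to 0.806 over its alternatives. The 61 heat shock genes and chaperones had a median of 0.01 and a camera direction below other genes (adjusted p = 0.782). hsp90 (Afu5g04170) had 1.43 ± 1.10, turning sign with median centring, and the isomerase gene fkbp1 (Afu6g12170) -2.01 ± 0.82. The 91 proteasome and ubiquitin genes had a median of -0.02 and the 34 ion transport and calcium genes one of -0.10, both at an adjusted p of 0.631. With median centring the heat shock and proteasome lists were called lower than other genes, at adjusted p of 0.0239 and 0.0177, within ranges of 0.0234 to 0.985 and 0.0177 to 0.951 over their alternatives. In the ribosomal, heat shock, proteasome, ion transport and glycolysis lists no member was called over all genes or adjusted over the list alone. Among 16 iron acquisition genes, the median was 0.04 (adjusted p = 0.828). Adjusted over the list alone 2 genes named as putative siderophore transporters passed, crmC (Afu3g13670) at 2.48 ± 2.65 and mirC (Afu2g05730) at -1.42 ± 0.02. The arrays differed widely for crmC, with 4.36 on array 1 and 0.60 on array 2.

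The 8 allergen genes had a median of 0.07 (adjusted p = 0.631), and with median centring the list was called lower (adjusted p 0.00147, within a range of 3.20e-04 to 0.900 over its alternatives). Asp f 2 was the 1 member called when adjusted over the list alone. The 54 genes of DNA replication and cell cycle had a median of 0.13 (adjusted p = 0.631) and no call in either adjustment. This list took in a putative tetracycline-efflux transporter (Afu5g07760) at -1.56 ± 0.03 through a part-word match. Markers of conidia or conidiating hyphae, which a 24 h culture could also hold, numbered 13, with 4 above 0, 9 below, a median of -0.10 and an adjusted p of 0.631. Their mean lay above 0, at 0.02, and 6 of the 13 were above the control spots in neither RNA. The regulator gene vosA (Afu4g10860) had -0.81 ± 0.26 and conJ (Afu6g03210) -0.995 ± 0.44, and no marker was called in either adjustment. ecm33 (Afu4g06820), which is a cell wall gene matched by its description, had 1.62 ± 0.05 and turned with median centring. Of the genes named with their lists, Afu1g00420, gliP and Afu2g00320 were not well above background in the untreated RNA, nor were Afu3g12370, mirC, vosA and conJ in the AMB RNA. Their log2 ratios are fitted values and not measured folds. For Afu3g12370 the bound was at least 3.10-fold lower. In their brighter RNA, Afu1g00420, Afu2g00320, vosA, conJ, gliJ and ncr1 were well above background on 1 of the 2 arrays only.

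**Figure D4:**
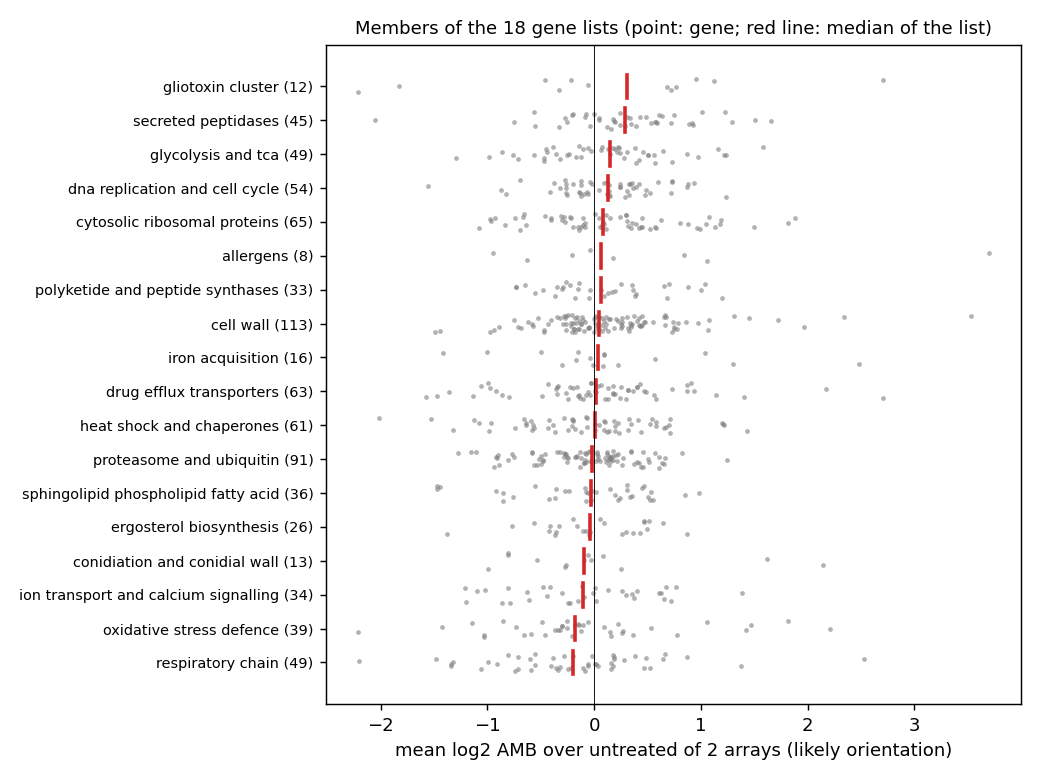
Mean log2 ratio of AMB over untreated on 2 arrays in the likely orientation for each measured member (gray points) of the 18 gene lists, with the number of members in brackets and the list median as a red line. The medians lie between -0.20 for the respiratory chain and 0.31 for the gliotoxin cluster, and no list passed camera after adjustment.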

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

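All tests in this part were chosen after the data were seen. Probes that the array files list as obsolete were left out of every comparison, yet 7 of the 349 were brighter than the 95th percentile of the control spots in all 4 channels. This is 2.01% (exact Clopper-Pearson 95% interval 0.810% to 4.09%), and 5.12% of the gene probes and 0 of 500 control spots, which allows up to 0.6%, passed likewise. Since that level is set by the control spots themselves, a test against all of them was set aside, and the level was taken from alternate control spots and counted in those left out. Then 0 of 250 control spots and 7 obsolete probes passed, whichever set gave the level. A count of 0 in 250 allows up to 1.2%. Fisher's exact test (two-sided) of these counts gave p = 0.0453 with either set, taking spots as independent, and was the last of several ways tried to compare them. In single channels, 27 and 26 obsolete probes exceeded that level in the red and green channels of array 1, and 40 and 66 did on array 2. On both arrays 1 obsolete probe was at least 2-fold lower with AMB in the orientation used, at log2 ratios of -2.06 and -2.45, against 0 control spots.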

How the results depend on the processing

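The foreground median, the control-spot filter, the centred value table, the neighbour subtraction, the GC correction and the part-word list were added after the data were seen. Genes past adjusted p 0.05 in limma numbered 10, and 8 with the centred value table, none of them shared. All 10 were among the 42 with offset 16, the 151 with scaling between arrays, the 65 with no dim filter, the 30 without the trend and the 26 with robust eBayes. Shared calls numbered 7 of 22 without background correction, 7 of 43 with median centring, 4 of 32 with plain subtraction (1088 genes tested), 1 of 1 with block loess, 5 of 277 with the value table as deposited and 8 of 96 with the control-spot filter (1416 genes tested). The count was 0 with both arrays read by their dye labels, the foreground median, neighbour subtraction and GC correction, where 259, 344, 530 and 524 genes had an unadjusted p under 0.05. Genes at least 2-fold in the same direction numbered 192, against 68 without background correction, 598 with median centring, 114 with block loess, 552 and 332 with the value table as deposited and centred, 34 by the dye labels and 116 with neighbour subtraction; elsewhere they stayed within 129 to 259. Of the 2-fold genes, 36.5% were higher with AMB, 48.5% without background correction, 5.69% with median centring, 68.3% with the value table as deposited and 2.41% with it centred. Lists past the threshold numbered 0, but 7 with median centring and the same 7 with the value table as deposited (oxidative stress, heat shock, gliotoxin, ribosomal, respiratory, proteasome and allergen genes), 5 of these with it centred (not heat shock and proteasome), 2 with the foreground median (secreted peptidases and ribosomal proteins), 1 with block loess and 1 without the trend (secreted peptidases in both, adjusted p 0.0188 and 0.0350, within a range of 0.0188 to 0.990 over its alternatives). The median of all genes lay at -0.18 with median centring, 0.49 with the value table as deposited and -0.15 with it centred.

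Turned lists, under median centring, the value table as deposited and the centred table in that order, were the gliotoxin cluster (medians -1.63, -1.01 and -1.66), ribosomal proteins (-1.41, -0.88 and -1.52) and allergens (-1.95, -1.61 and -2.25). By the dye labels, tef1 stood at -0.44, Afu5g10920 at -0.26 and Afu5g00930 at -0.33, all at an adjusted p of 0.999. Median centring and both forms of the value table lack the loess on brightness, and the first differs from the main setting in that step alone. The turned lists held few dim genes. Above the control spots in neither RNA were 0 of 12 gliotoxin, 0 of 8 allergen and 9 of 65 ribosomal genes. Beyond this, the cause of these changes was not tested, except that reading both arrays by their dye labels turns array 2. Each array alone held 889 to 1450 genes at least 2-fold, a value with no test, since 1 array leaves no spread; a count past adjusted p cannot be given. Against random lists matched on brightness, the secreted peptidase median lay at percentile 97.6 on array 1 and 99.8 on array 2, and the ergosterol median at 7.16 and 95.8. Keeping flagged spots and a correlation between duplicate spots were not run, since no spot is flagged and each probe has 1 spot. The part-word matches did not change the DNA replication result. No paired analysis was possible because each array already pairs both RNAs and the labels give 1 group. Signal over background limits the data, since 2988 of the 7391 tested genes were above the control spots in neither RNA.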

Other observations

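The genes of the first paragraphs and the tests of this part were chosen after the data were seen, those of conidial markers and of brightness in the whole gene set also after related values. The gliotoxin genes are members of a list fixed beforehand, and the count with array 2 not turned was planned. Directions are those of the orientation used, and none of the genes of the first paragraphs passed the limma test. The zinc transporter gene zrfC (Afu4g09560), which lies next to the Asp f 2 gene in the annotation, had a log2 ratio of 1.71 ± 0.25 (SD, n = 2), but stood at -1.27 with median centring in place of loess. A putative Ctr copper transporter (Afu2g03730) was at 3.12 ± 2.42, and at 0.004 with median centring. Actin (Afu6g04740) was at 1.87 ± 1.18 and beta-tubulin (Afu7g00250) at 1.71 ± 0.42, and with median centring they stood at -0.53 and 0.04. Subunits of the actin-nucleating Arp2/3 complex had opposite signs, with Afu1g13330 at 1.88 ± 1.19 and Afu6g06500 at -1.47 ± 0.35, the latter not well above background in the AMB RNA and so bounded at at least 1.54-fold lower.

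A universal stress protein (Afu2g09500), not well above background in the untreated RNA and so bounded at at least 1.51-fold higher, had 1.74 ± 0.20, and the catalase-peroxidase cat2 (Afu8g01670), a member of the oxidative stress list, 1.43 ± 0.28, which turned to -1.14 with median centring. The MAP kinase Osm1 (Afu1g12940) had -1.71 ± 0.60 and a histidine phosphotransmitter (Afu4g10280), which belongs to the same class of pathway, -1.70 ± 0.31. A trehalose-phosphate synthase subunit (Afu3g05650) had -1.73 ± 0.58, caleosin (Afu5g13750), a lipid droplet protein, -1.98 ± 0.36, the blue light-inducible Bli-3 (Afu1g14040) -2.45 ± 1.46 and a sterol O-acyltransferase (Afu1g06040), which stores sterols as esters, -2.97 ± 1.92. Osm1, the trehalose gene and caleosin were not well above background in the AMB RNA, with bounds of at least 1.96-fold, 1.42-fold and 1.58-fold lower.

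More genes were at least 2-fold the same way with array 2 turned (192) than with it not turned (34). The brightest of 5 equal groups of genes held 120 of the 192, and the turned ratios correlated there at r = 0.354 across genes, against 0.100, 0.067, 0.054 and 0.048 in the remaining 4 groups from the dimmest up. A test built on that correlation was dropped, since the group stands out by the pattern itself. In the remaining groups 10, 20, 17 and 25 genes were at least 2-fold the same way, against 4, 5, 7 and 6 in opposite ways. In its place each array was centred within 148 bins of genes of like brightness, which changed the 2-fold status of 58 genes and left 174 the same way and 31 in opposite ways. The ratio of turned to unturned counts was then 5.61, from 5.65, which argues against a remaining trend with brightness as the whole cause. The loess had already removed a trend with brightness, and the median shift here was 0.077 on the log2 scale. The test therefore concerns only what the loess had left and does not weigh other effects bound to brightness. Position on the slide and GC content do not account for the whole of the pattern either, with ratios of 5.52 after neighbouring spots were subtracted and 5.31 after a GC correction. Subtracting neighbouring spots lowered both counts, to 116 the same way and 21 in opposite ways. It kept 86 of the 192 genes, so a part from position stays open. Arrays of opposite orientation would give such counts, but the counts do not say which array is the swapped one. Nor do they settle that the arrays were swapped. Gene spots with many saturated pixels lay in red on array 1 (28) and in green on array 2 (44). The dimmer channel changed too, from green on array 1 to red on array 2. An effect of saturation or dim signal could therefore also favour the turned count, and none of these tests reaches it. An effect of AMB stays open as a biological hypothesis that 2 arrays cannot separate from other differences between the cultures.

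Genes with fitted ratios at least 2-fold lower with AMB on both arrays included LEA and HHE domain genes, families often abundant in resting cells. A hypothesis is that the untreated culture may have held more conidia or conidiating cells. The 7 of 13 conidial markers above the control spots had a median log2 ratio of 0.0844 (quartiles -0.54 and 0.93). The cut for a set lower with AMB was a median of -1 or below. It was chosen after the data were seen, and a smaller drop of the markers would not reach it. Without ecm33, a cell wall gene matched only by its description, the median of the remaining 6 was -0.09 (quartiles -0.68 and 0.21). Of all 13 markers, 5 were lower on both arrays, and ecm33 was the 1 that was higher on both. The median of the 13 was -0.36 on array 1 and -0.19 on array 2, so the medians leaned lower. With so few markers, many near the background, this hypothesis and an effect of the drug cannot be told apart. With the orientation exchanged, the hypothesis would apply to the AMB culture.

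Within the gliotoxin cluster, gliA and gliZ had fitted ratios of at least 2-fold higher and gliG and gliJ of at least 2-fold lower, gliJ with a bound of only 1.47-fold. With median centring all 4 lay below 0, gliA at -0.45, gliZ at -1.32, gliG at -4.40 and gliJ at -1.60, so the opposite directions depend on the loess step. Position on the slide is argued against, since 3 of the 4 kept a 2-fold ratio in the same direction after neighbouring spots were subtracted; gliZ had 0.94 on array 1. The brightness of the cluster's probes stays open as a candidate explanation, because 5.46% of random sets matched on brightness held 4 or more such genes, with a mean of 1.57. A differential response of the cluster's genes to AMB was not tested apart from this.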
